A study of Mus musculus with 24 samples.

How the data were processed

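The 24 libraries came from mouse pleural fluid cells and digested pleural tumor cells under 4 treatments, 3 libraries per group, and each sample's group was taken from its title. Messenger RNA was selected by poly-A and libraries were made with a kit that does not mark strand, per the labels' protocols, so overlapping and antisense genes cannot be told apart. The deposited table holds 1 FPKM value (fragments scaled by gene length and library depth) per gene and library, for 54505 genes. The submitters' processing notes name fastp, STAR, featureCounts and DESeq2 and the build mm9, without versions or roles. The coordinates in the table match GRCm38 for 53474 of 54383 gene IDs found in GENCODE M21, so they are given as GRCm38. Multiplying each FPKM by gene length and by 1 factor per library, fitted to the low values, gave whole reads, within 0.01 read, for 99.92 to 99.97% of values per library. The recovered totals range from 14579080 to 26847338 reads. These factors were proportional to median-of-ratios size factors. 27 symbols stored as dates were matched to gene names by their IDs.

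For 21 genes the values were not whole reads at the listed length, 9 in fluid and 19 in tumor. They include Ifnb1 in both tissues, Nos2 in fluid, and Vegfa and Ifng in tumor, and these genes were left out of every test in the tissues affected. Tests were run on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using linear models with moderated variances and a trend with the mean. The adjusted p is Benjamini-Hochberg, two-sided, and a gene changed when it was under 0.05. Comparisons between treatments used 1 fit per tissue over 12 libraries, with genes at an FPKM of at least 1 in at least 3 libraries, and tissue differences used 1 fit over all 24. An exact permutation test of 3 libraries against 3 cannot give p below 0.1, so the calls rest on the spread estimated over all groups and genes. Gene lists of cell types and pathways, 44 in number, were tested with camera at the preset correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of each comparison. Of 218 calls with the preset correlation, 3 held with an estimated one. Those are mast cell markers for the combination against LNP-CDN in fluid, and regulatory T cell markers and mature migratory dendritic cell genes in the tissue difference for anti-PD-L1. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

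The lists, tests, naming rule and most alternatives were fixed before the data were examined. The rule names up to 6 higher and 6 lower genes per comparison between treatments. These have the largest log2 change among genes past the threshold, no overlap between the groups and a mean FPKM of at least 1 in the higher group, and predicted, ribosomal, mitochondrial and antigen receptor segment symbols are left out. It adds up to 4 members with the smallest p of each list past the threshold, and 16 core genes whatever their result. Tissue differences in a treatment's effect take 3 higher and 3 lower genes. The text names a part of the genes chosen. On simulated reads with 200 changed genes, the fit for LNP-CDN against PBS in fluid recovered 42.4% at 1.5-fold, 70.1% at 2-fold, 93.8% at 4-fold, with 4.90% of calls false over 13098 genes. For tumor it recovered 65.7% at 1.5-fold, 74.2% at 2-fold, 98.5% at 4-fold, with 6.51% of calls false over 12922 genes, and for the tissue difference 41.8% at 1.5-fold, 57.6% at 2-fold, 81.5% at 4-fold, with 6.30% of calls false over 14809 genes. The simulated changes were put only on genes above a minimum mean read count. Each gene was drawn independently, with no variation shared between genes, and far fewer genes changed than in most fluid comparisons. These shares therefore need not hold for the real data. Replicates of 1 group differed by more than sampling noise (chi-square per degree of freedom 4.90 to 95.7), so none was counted as a duplicate. Alternatives were a pseudocount of 0.1, no filter, rescaling, only the 6 libraries compared, a replicate block, and each library left out. Added after seeing the data were limma-voom on recovered reads, total-read scaling, keeping the affected genes, and leaving out genes on X and Y.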

Results

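RNA was sequenced from 24 libraries of mice carrying malignant pleural effusions. Lewis lung carcinoma cells, a mouse lung cancer line, had been grown in the pleural cavity of C57BL/6 mice. On day 11 the mice received into the pleural cavity either phosphate-buffered saline (PBS), the antibody anti-PD-L1 at 30 µg, liposomal nanoparticles carrying the cyclic dinucleotide cGAMP at 1 µg (LNP-CDN, an agonist of the STING pathway), or both agents. On day 13 cells were collected from the pleural fluid and from digested pleural tumors, which gave 8 groups of 3 libraries. The labels give 3 mice per treatment and do not say whether fluid and tumor libraries came from the same mice. The reads recovered per library ranged from 14579080 to 26847338. Between 12202 and 12694 genes per library reached an FPKM of at least 1. Changes below are log2 differences of FPKM + 1, 3 libraries against 3, which understate the change of low genes. Their standard errors use the spread estimated over all groups of the fit. Levels are mean FPKM ± SD, n = 3. Coordinates are those of the deposited table, which match GRCm38 for 53474 of the 54383 genes compared.

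The markers of sex were not spread evenly over the groups. In fluid, Y-linked Ddx3y (chromosome Y, 1260771 to 1286629) lay at 22.7 ± 0.999 in the anti-PD-L1 libraries and at no more than 0.0283 in any other fluid library. X-linked Xist was 12.5 ± 6.56 there and 62.2 ± 9.14 in PBS fluid. In tumors, Ddx3y ranged from 3.27 to 3.44 in the anti-PD-L1 libraries, reached 3.55 in PBS replicate 1, and was at most 0.0205 in the other tumor libraries. Xist did not mirror Ddx3y in tumors, at 68.2 ± 4.61 with anti-PD-L1, 66.9 ± 2.11 with LNP-CDN and 104 in PBS replicate 1, the highest of the 24 libraries. In fluid, sex and treatment cannot be told apart for the anti-PD-L1 group. In tumors PBS replicate 1 is the 1 library outside the anti-PD-L1 group with such reads, and no fit with a term for sex was made.

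**Figure D1:**
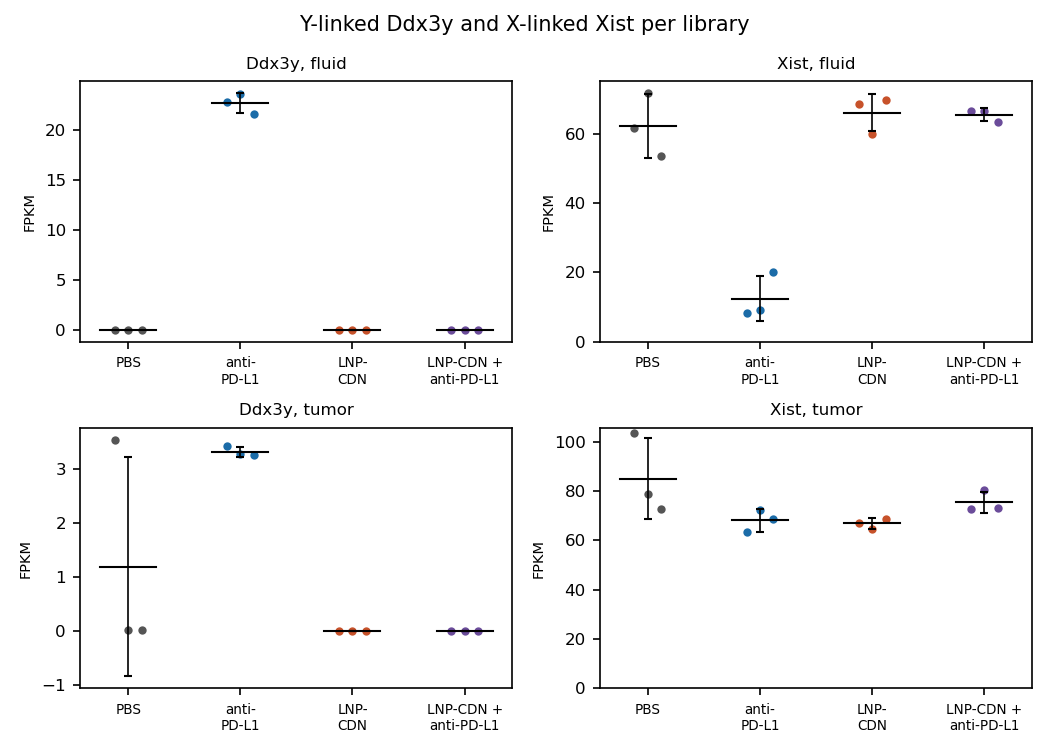
FPKM of Y-linked Ddx3y and X-linked Xist (vertical axes) in the 4 treatment groups of each tissue, with 1 point per library, a line at the mean and bars of 1 SD. Ddx3y lies at 21.6 to 23.6 in the fluid anti-PD-L1 libraries, and tumor PBS replicate 1 at 3.55 stands with the tumor anti-PD-L1 libraries.

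The comparison of LNP-CDN with PBS in pleural fluid addresses the response of effusion cells to the STING agonist. Of the genes chosen by the naming rule, the largest increases were those of the interferon-induced Ifit3 (4.46 ± 0.35), Ifit2 (4.32 ± 0.42), Ifit1bl1 (4.09 ± 0.39) and Ifit3b (3.93 ± 0.30), the glycoprotein gene Gpnmb (3.74 ± 0.15), and interferon-induced Ifi44 (3.57 ± 0.22). Ifit3 (chromosome 19, 34583531 to 34588731) went from 9.15 ± 1.22 to 232 ± 93.1. Among the core genes, Ifit1 (3.08 ± 0.27), Isg15 (2.67 ± 0.28) and Cxcl10 (3.39 ± 0.31), a chemokine for activated T cells, rose as well. Of the interferon-stimulated genes, 39 of 39 rose and 39 did so adjusted over the list alone (camera adjusted p = 2.23e-32, and adjusted p = 0.223 with an estimated correlation). Of the interferon-gamma response genes, 18 of 23 rose and 18 did so adjusted over the list alone, among them Irgm2 (1.55 ± 0.15) and Gbp6 (1.89 ± 0.24) (adjusted p = 3.55e-09, and adjusted p = 0.383 with an estimated correlation). Of the MHC class I genes, 16 of 20 rose and 18 did so adjusted over the list alone, with H2-Q6 (2.26 ± 0.16) and H2-Q7 (1.98 ± 0.18) as examples (adjusted p = 8.47e-11, and adjusted p = 0.280 with an estimated correlation). Of the cytotoxic effector genes, 7 of 13 rose and 8 did so adjusted over the list alone, with Ccl5 (2.77 ± 0.32), Gzmb (2.77 ± 0.56) and Gzma (2.01 ± 0.30) (adjusted p = 0.00176, and adjusted p = 0.415 with an estimated correlation). Gzmb, a granule protease of killer cells, went from 7.62 ± 0.445 to 59.8 ± 19. Of the T cell markers, 6 of 16 fell and 8 did so adjusted over the list alone, with Cd3e (-0.81 ± 0.18) and Tcf7 (-1.19 ± 0.27) (adjusted p = 0.000879, and adjusted p = 0.415 with an estimated correlation).

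In the same comparison, of the macrophage markers, 8 of 15 rose and 8 did so adjusted over the list alone, such as Ms4a7 (1.89 ± 0.39) and Trem2 (1.14 ± 0.25), while 1 fell (adjusted p = 0.00176, and adjusted p = 0.415 with an estimated correlation). The scavenger receptor Cd163 (chromosome 6, 124304656 to 124330527) dropped from 334 ± 35 to 33 ± 4.13, a change of -3.30 ± 0.11. Other large decreases were Lyve1 (-4.57 ± 0.42), the heme synthesis gene Alas2 (-4.40 ± 0.40), the B cell receptor component Cd79a (-3.29 ± 0.57), the neutrophil gene Retnlg (-3.15 ± 0.51) and Btla (-3.06 ± 0.31). Of the alternatively activated macrophage genes, 8 of 15 fell and 9 did so adjusted over the list alone, including Mrc1 (-0.98 ± 0.13) and Arg1 (-1.12 ± 0.19) (adjusted p = 2.19e-05, and adjusted p = 0.150 with an estimated correlation). Arg1, an arginine-consuming enzyme of such macrophages, went from 2777 ± 233 to 1274 ± 107 and was not past the threshold with no filter on low values. Of the B cell markers, 10 of 11 fell and 10 did so adjusted over the list alone (adjusted p = 3.76e-07, and adjusted p = 0.280 with an estimated correlation). Of the MHC class II genes, 9 of 12 fell and 10 did so adjusted over the list alone, such as H2-Eb1 (-2.45 ± 0.30) (adjusted p = 6.28e-07, and adjusted p = 0.245 with an estimated correlation). Of the conventional dendritic cell markers, 9 of 11 fell and 9 did so adjusted over the list alone, such as Flt3 (-1.94 ± 0.11) (adjusted p = 5.64e-07, and adjusted p = 0.223 with an estimated correlation). Of the mitochondrially encoded genes, 10 of 13 fell and 13 did so adjusted over the list alone (adjusted p = 1.31e-09, and adjusted p = 0.223 with an estimated correlation). Their share of reads was 0.840 to 0.904% in PBS fluid and 0.307 to 0.429% with LNP-CDN.

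In all, 3518 of 13518 genes changed in fluid with LNP-CDN, 1853 higher and 1665 lower. The larger side of this split turned with total-read scaling, chosen after seeing the data, to 1619 higher and 1904 lower, and with no filter on low values to 1489 higher and 1521 lower. The count was 2234 without fluid PBS replicate 1 and 2202 without fluid PBS replicate 3. Of the 84 genes chosen by the naming rule that passed, 5 lost their call with at least 1 library left out. The other 79 kept it wherever they were tested, and without a fluid PBS library 81 of the 84 were tested. The PD-L1 gene Cd274 (1.12 ± 0.27) rose but reached adjusted p = 0.0504 without fluid PBS replicate 3. Without that library Vegfa (-0.90 ± 0.23) reached adjusted p = 0.0635 and the STING gene Tmem173 (0.72 ± 0.22) adjusted p = 0.111. Neither Cd8a (-0.85 ± 0.42) nor S100a8 (-1.46 ± 0.50) passed.

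Anti-PD-L1 against PBS in fluid asks what the antibody alone does, and here it also compares libraries with Y-linked reads against libraries without them. Apart from the Y-linked Ddx3y (4.54 ± 0.09), Eif2s3y (4.25 ± 0.13) and Uty (1.99 ± 0.15), the largest increases were the interferon-inducible GTPases Gbp2b (2.87 ± 0.68) and Iigp1 (2.55 ± 0.41), and Mamdc2 (1.86 ± 0.33). The largest decreases were the platelet chemokine Ppbp (-3.69 ± 0.58), the neutrophil chemokine Cxcl3 (-3.39 ± 0.49), Retnlg (-3.28 ± 0.51), Rdh12 (-2.71 ± 0.28), Cd79a (-2.68 ± 0.57) and the neutrophil collagenase Mmp8 (-2.47 ± 0.41). Of the neutrophil markers, 13 of 16 fell and 14 did so adjusted over the list alone (adjusted p = 3.44e-10, and adjusted p = 0.216 with an estimated correlation). The alarmin S100a8 (-2.22 ± 0.50) went from 828 ± 171 to 182 ± 62.1. Of the B cell markers, 10 of 11 fell and 11 did so adjusted over the list alone (adjusted p = 3.71e-10, and adjusted p = 0.216 with an estimated correlation). Of the regulatory T cell markers, 6 of 6 fell and 6 did so adjusted over the list alone, including Ctla4 (-1.22 ± 0.26) (adjusted p = 2.47e-05, and adjusted p = 0.0925 with an estimated correlation). Foxp3 was below the filter and not tested, at 0.956 ± 0.0467 in PBS and 0.651 ± 0.0216 with anti-PD-L1. The T cell marker, immune checkpoint and T cell activation lists were also called, with the preset correlation only. Whether the fall is particular to regulatory T cells was not tested. Of the NK cell markers, 8 of 13 fell and 11 did so adjusted over the list alone, including Klrb1b (-1.36 ± 0.21) and Ncr1 (-0.92 ± 0.15) (adjusted p = 1.29e-06, and adjusted p = 0.216 with an estimated correlation). Of the cell cycle genes, 12 of 24 rose and 21 did so adjusted over the list alone, including Mcm3 (0.60 ± 0.10) and E2f1 (0.53 ± 0.07) (adjusted p = 1.70e-09, and adjusted p = 0.263 with an estimated correlation). Of the interferon-gamma response genes, 13 of 23 rose and 17 did so adjusted over the list alone, including Gbp3 (1.43 ± 0.23) and Tgtp2 (1.48 ± 0.26) (adjusted p = 2.85e-08, and adjusted p = 0.273 with an estimated correlation). The core genes Cd274 (1.08 ± 0.27), Cxcl9 (1.12 ± 0.32) and Cxcl10 (1.09 ± 0.31) rose, while Ifit1 (0.12 ± 0.27), Isg15 (-0.20 ± 0.28) and Gzmb (-0.05 ± 0.56) did not pass.

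Here 1751 of 13518 genes changed, 739 higher and 1012 lower. Scaling to total reads, an alternative chosen after seeing the data, moved that split to 523 higher and 1277 lower. Without genes on X and Y, 1689 genes changed. Without fluid anti-PD-L1 replicate 3 the larger side turned, with 968 higher and 821 lower, and without fluid PBS replicate 1 it was 225 higher and 499 lower. The count was 724 without fluid PBS replicate 1, 1137 without fluid PBS replicate 2, 732 without fluid PBS replicate 3, and 1043 with only the 6 libraries compared. Of the 87 named genes that passed, 28 lost their call with at least 1 library left out. The highest adjusted p with 1 library left out came without fluid PBS replicate 3 for several, at 0.0764 for Gbp2b, 0.0599 for Cd79a, 0.0692 for S100a8, 0.0657 for Ctla4, 0.0998 for Cd274 and 0.140 for Cxcl10. For Cxcl9 it was 0.123 without fluid PBS replicate 1.

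With both agents, fluid cells were compared with PBS. The leading genes were interferon-induced: Ifit1bl1 (4.60 ± 0.39), Ifit3 (4.40 ± 0.35), Ifit2 (4.37 ± 0.42), Ifit3b (3.65 ± 0.30), Ifi44 (3.63 ± 0.22) and Apol9b (3.47 ± 0.16). Decreases were led by Lyve1 (-4.98 ± 0.42), Alas2 (-4.80 ± 0.40), the coagulation factor F5 (-3.23 ± 0.74), Rdh12 (-3.19 ± 0.28), Retnlg (-3.18 ± 0.51) and Cd163 (-3.08 ± 0.11). Of the interferon-stimulated genes, 39 of 39 rose and 39 did so adjusted over the list alone (adjusted p = 2.75e-29, and adjusted p = 0.300 with an estimated correlation). Of the MHC class I genes, 16 of 20 rose and 19 did so adjusted over the list alone (adjusted p = 3.40e-10, and adjusted p = 0.377 with an estimated correlation). Of the cell cycle genes, 20 of 24 fell and 21 did so adjusted over the list alone, with Ccnb2 (-1.32 ± 0.16) and Mcm3 (-0.63 ± 0.10) (adjusted p = 2.90e-08, and adjusted p = 0.377 with an estimated correlation). Of the immediate early and heat shock genes, 11 of 15 fell and 11 did so adjusted over the list alone, with Egr1 (-1.72 ± 0.24) and Dusp1 (-1.63 ± 0.27) (adjusted p = 0.000863, and adjusted p = 0.377 with an estimated correlation). Of the core genes, Cxcl10 (2.95 ± 0.31), Gzmb (2.61 ± 0.56), Cd274 (1.13 ± 0.27) and Tmem173 (0.98 ± 0.22) rose, and Arg1 (-1.15 ± 0.19), Mrc1 (-1.06 ± 0.13) and Vegfa (-1.34 ± 0.23) fell. With no filter on low values Arg1 was not past the threshold. Of the mitochondrially encoded genes, 10 of 13 fell and 10 did so adjusted over the list alone (adjusted p = 3.82e-08, and adjusted p = 0.300 with an estimated correlation), and their share of reads was 0.310 to 0.349% against 0.840 to 0.904% in PBS. Of the macrophage markers, 7 of 15 rose and 7 did so adjusted over the list alone, while 1 fell (adjusted p = 0.00808, and adjusted p = 0.510 with an estimated correlation). The count was 4064 genes, 2111 higher and 1953 lower. It was 2006 higher and 2055 lower with total-read scaling, and 1824 higher and 1854 lower with no filter. Of 93 named genes that passed, 7 lost their call with at least 1 library left out. The other 86 kept it wherever they were tested, and without a fluid PBS library 90 of the 93 were tested.

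Against anti-PD-L1 alone, which carries the same difference in sex markers, the combination gave 5048 changed genes in fluid, 2490 higher and 2558 lower, or 4882 without genes on X and Y. The split was 2695 higher and 2340 lower with total-read scaling and 2753 higher and 2652 lower without fluid anti-PD-L1 replicate 1, both with the larger side turned. Increases were led by Ifit1bl1 (4.73 ± 0.39), Ifit3 (4.01 ± 0.35), the endothelial lipase Lipg (3.80 ± 0.38), Ly6i (3.77 ± 0.29), Ccl5 (3.66 ± 0.32) and Ifit3b (3.64 ± 0.30). The monocyte antigen Ly6c2 (3.46 ± 0.33) and the chemokine receptor Ccr2 (1.61 ± 0.13) rose too. Decreases were led by Lyve1 (-5.76 ± 0.42), Y-linked Ddx3y (-4.56 ± 0.09), Alas2 (-4.42 ± 0.40), Y-linked Eif2s3y (-4.24 ± 0.13), Adm (-3.05 ± 0.33) and Cd163 (-2.91 ± 0.11). Of the cell cycle genes, 24 of 24 fell and 24 did so adjusted over the list alone (adjusted p = 1.14e-14, and adjusted p = 0.576 with an estimated correlation). Of the cytotoxic effector genes, 10 of 13 rose and 11 did so adjusted over the list alone, including Gzma (2.77 ± 0.30) and Prf1 (1.85 ± 0.38) (adjusted p = 2.71e-05, and adjusted p = 0.576 with an estimated correlation). Of the mitochondrially encoded genes, 12 of 13 fell and 13 did so adjusted over the list alone (adjusted p = 8.49e-09, and adjusted p = 0.576 with an estimated correlation), with a share of reads of 0.310 to 0.349% against 0.754 to 1.05% with anti-PD-L1.

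Adding anti-PD-L1 to LNP-CDN changed 0 of 13518 genes in fluid by limma, with 761 genes at an unadjusted p under 0.05 and 0 by limma-voom on the recovered reads. Ddx3y was at most 0.0283 in both groups. Among interferon-stimulated genes, Ifit1 differed by -0.14 ± 0.27 and Isg15 by -0.08 ± 0.28. The lowest adjusted p, 0.0613, belonged to the mast cell protease Tpsb2 (-1.36 ± 0.19), at 4.26 ± 0.423 with LNP-CDN and 1.05 ± 0.180 with both. Mast cell markers were lower as a list, with 0 of 5 passing and 3 adjusted over the list alone (adjusted p = 2.01e-09, and adjusted p = 0.0282 with an estimated correlation). Other lists were also lower with no member passing: fibroblast markers, 2 of 13 adjusted over the list alone (adjusted p = 3.89e-07, and adjusted p = 0.552 with an estimated correlation), immediate early and heat shock genes, 4 of 15 (adjusted p = 1.14e-07, and adjusted p = 0.552 with an estimated correlation), and cell cycle genes, 0 of 24 (adjusted p = 3.19e-07, and adjusted p = 0.621 with an estimated correlation). Monocyte and B cell markers were higher as lists, though neither with an estimated correlation. These calls were lost without LNP-CDN replicate 3 (monocyte, camera adjusted p = 0.0589) and without combination replicate 3 (B cell, 0.103). The imprinted RNA H19 (chromosome 7, 142575529 to 142578143), chosen after its values were seen, was 5.09 ± 0.823 with LNP-CDN and 0.154 ± 0.00905 with both. It passed with a pseudocount of 0.1 (adjusted p = 0.00351), as the 1 gene there. With only the 6 libraries compared, the 4 genes passing were H19, Tpsb2, Aldh1a2 and Car1, each lower with both agents. Without a filter on low values 2 genes passed, Gm11592 and Mir7015, and these too were named after their values were seen.

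**Figure D2:**
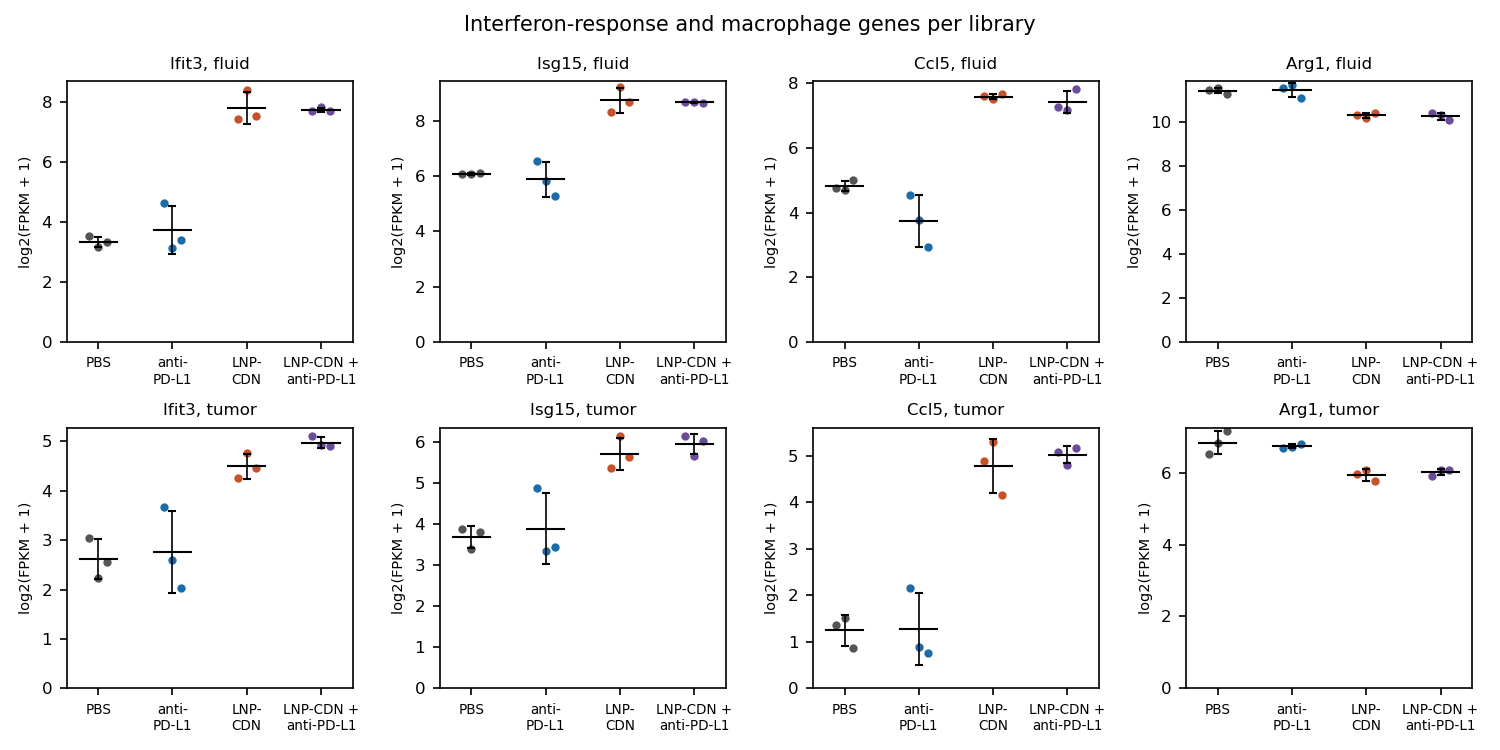
log2(FPKM + 1) (vertical axes) of Ifit3, Isg15, Ccl5 and Arg1 in the 4 treatment groups, fluid in the upper panels and tumor in the lower panels, with 1 point per library, a line at the mean and bars of 1 SD. In both tissues the Ifit3, Isg15 and Ccl5 points with LNP-CDN, alone or combined, lie above those of PBS, and the Arg1 points lie below them.

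In tumors, LNP-CDN against PBS raised the T cell chemokine Ccl5 (3.53 ± 0.36) (chromosome 11, 83525778 to 83530518) most, from 1.41 ± 0.520 to 27.9 ± 10.7. The interferon regulator Irf7 (2.20 ± 0.29), Ifi27l2a (2.14 ± 0.21), Isg15 (2.02 ± 0.35), Ifit3 (1.88 ± 0.34) and the carbonic anhydrase Car3 (1.83 ± 0.24) followed. Car3 was examined with the muscle and liver genes below and is not counted here as an interferon gene. It was at most 0.0861 in LNP-CDN fluid, where interferon-induced genes rose. The scavenger receptor Marco (-2.11 ± 0.15) (chromosome 1, 120474538 to 120505024) fell most, from 23.8 ± 4.69 to 4.77 ± 1.12. Further decreases were Mir6400 (-1.47 ± 0.28), the cold-inducible RNA-binding gene Cirbp (-1.19 ± 0.17), the neutrophil chemokine Cxcl2 (-1.03 ± 0.24), F13a1 (-0.92 ± 0.20), Cp (-0.91 ± 0.19) and Arg1 (-0.90 ± 0.14). Mir6400 is a short microRNA gene at 2.51 ± 1.37 in PBS, so that few reads set its value, and it was not past the threshold with a pseudocount of 0.1 or by limma-voom. Of the interferon-stimulated genes, 26 of 39 rose and 38 did so adjusted over the list alone (adjusted p = 1.74e-29, and adjusted p = 0.621 with an estimated correlation). Of the MHC class I genes, 4 of 20 rose and 15 did so adjusted over the list alone, with H2-Q6 (1.09 ± 0.20) (adjusted p = 1.12e-08, and adjusted p = 0.621 with an estimated correlation). Of the cytotoxic effector genes, 3 of 8 rose and 6 did so adjusted over the list alone, with Gzma (1.51 ± 0.22) (adjusted p = 0.000143, and adjusted p = 0.621 with an estimated correlation). Skeletal muscle genes were higher as a list with 0 of 10 passing (adjusted p = 0.00519, and adjusted p = 0.645 with an estimated correlation), a call lost without PBS replicate 3 (adjusted p = 0.0774) and without LNP-CDN replicate 3 (adjusted p = 0.106), and Acta1 ranged from 0.863 to 95.5 within the LNP-CDN group. Of the adipocyte markers, 1 of 4 rose and 2 did so adjusted over the list alone, the 1 over all genes being Adipoq (1.20 ± 0.24) (adjusted p = 0.0118, and adjusted p = 0.621 with an estimated correlation), and without PBS replicate 2 the list reached adjusted p = 0.0505. Alb, a liver gene, was 15.3 in LNP-CDN replicate 1 and 0.0153 in replicate 2. Of the core genes, Cd274 (0.49 ± 0.24), Ifit1 (1.47 ± 0.37), Cxcl10 (1.62 ± 0.41), Gzmb (1.26 ± 0.51) and Nos2 (0.15 ± 0.27) did not pass.

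The count in tumors with LNP-CDN was 442 of 13173 genes, 249 higher and 193 lower. The larger side turned with total-read scaling, to 210 higher and 236 lower, and without LNP-CDN replicate 2, to 87 higher and 96 lower. The count was 147 without tumor PBS replicate 1, the library with Y-linked reads, 52 without PBS replicate 2, and 94, 183 and 24 without LNP-CDN replicates 1, 2 and 3. It was 98 with no filter on low values and 106 with only the 6 libraries compared. Of 26 named genes that passed, 7 kept their call in every run with 1 library left out that tested them. Ccl5, Irf7, Ifi27l2a and Marco were among these 7. The highest adjusted p with 1 library left out came without LNP-CDN replicate 3 for most of the others, at 0.0688 for Isg15, 0.0756 for Ifit3, 0.0559 for Arg1, 0.0559 for Cirbp and Gzma, 0.104 for Mir6400, 0.141 for F13a1, 0.118 for Cp, 0.103 for Adipoq and 0.102 for H2-Q6. Without LNP-CDN replicate 1 it was 0.131 for Cxcl2.

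Anti-PD-L1 against PBS in tumors gave 0 changed genes of 13173 by limma, 821 at an unadjusted p under 0.05, and 0 by limma-voom. The tumor anti-PD-L1 libraries and PBS replicate 1 carry Y-linked reads, and the other PBS libraries do not. The smallest p values in the neutrophil list were those of Retnlg (-1.38 ± 0.24), S100a9 (-1.12 ± 0.22) and S100a8 (-1.18 ± 0.24), and neutrophil markers were lower as a list, with 0 of 14 passing and 9 adjusted over the list alone (adjusted p = 7.52e-10, and adjusted p = 0.538 with an estimated correlation). S100a8 was 28.6 ± 2.62 in PBS and 12 ± 1.08 with anti-PD-L1. Interferon-gamma response genes were higher as a list, with 0 of 22 passing and 0 adjusted over the list alone (adjusted p = 5.24e-09, and adjusted p = 0.801 with an estimated correlation). The interferon-stimulated and MHC class II lists were also called higher, but not with an estimated correlation. Without anti-PD-L1 replicate 1 both turned lower, at camera adjusted p = 0.00490 and 0.851. Skeletal muscle genes were higher as a list, with 0 of 10 passing and 0 adjusted over the list alone (adjusted p = 0.00362, and adjusted p = 0.801 with an estimated correlation), a call lost without PBS replicate 3 (adjusted p = 0.156) and without anti-PD-L1 replicate 2 (adjusted p = 0.306). That anti-PD-L1 library had Acta1 at 34.7, Tnnt3 at 18.7 and the liver gene Alb at 27.8, where Acta1 was 15.5 ± 17.2 over the group and 1.63 ± 2.34 in PBS. Without tumor PBS replicate 1, 2 genes passed, Y-linked Ddx3y and Eif2s3y. With only the 6 libraries compared, 2 passed, S100a8 (lower) and Mir7027 (higher), and with no filter 1, Gm25758. These few genes were named after their values were seen.

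The combination against PBS in tumors again raised Ccl5 (3.78 ± 0.36), Irf7 (2.51 ± 0.29), Ifit3 (2.37 ± 0.34), Ifi27l2a (2.34 ± 0.21), Isg15 (2.25 ± 0.35) and the antiviral Oas2 (2.13 ± 0.21). Mir6400 (-1.74 ± 0.28), Marco (-1.34 ± 0.15), Cxcl2 (-1.33 ± 0.24), Ctgf (-0.83 ± 0.16), Arg1 (-0.82 ± 0.14) and Rdh12 (-0.80 ± 0.15) fell. Of the interferon-stimulated genes, 28 of 39 rose and 39 did so adjusted over the list alone (adjusted p = 9.43e-51, and adjusted p = 0.336 with an estimated correlation). Of the hypoxia and glycolysis genes, 2 of 15 fell and 8 did so adjusted over the list alone, namely Pdk1 (-0.56 ± 0.08) and Egln3 (-0.64 ± 0.09) (adjusted p = 8.13e-09, and adjusted p = 0.445 with an estimated correlation). Skeletal muscle genes were higher as a list, with 0 of 10 passing (adjusted p = 0.00560, and adjusted p = 0.712 with an estimated correlation), a call lost without PBS replicate 3 (adjusted p = 0.0889) and without combination replicate 1 (adjusted p = 0.130). The count was 156 genes, 116 higher and 40 lower. It was 35 without tumor PBS replicate 2, and 25, 55 and 50 without replicates 1, 2 and 3 of the combination. It was 52 with no filter and 264 by limma-voom. Of 18 named genes that passed, 11 lost their call with at least 1 library left out. The highest adjusted p of these came without combination replicate 1, at 0.0526 for Ifit3, 0.0916 for Arg1, 0.0525 for Pdk1, 0.0526 for Egln3 and 0.0721 for Mir6400. Without PBS replicate 2 it reached 0.0743 for Isg15 and 0.112 for Cxcl2. It reached 0.121 for Ctgf without combination replicate 2 and 0.112 for Rdh12 without replicate 3.

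Against anti-PD-L1 alone, the combination in tumors gave 204 changed genes, 153 higher and 51 lower, led by Ccl5 (3.76 ± 0.36), Ifi27l2a (2.44 ± 0.21), Oas2 (2.29 ± 0.21), Irf7 (2.24 ± 0.29) and Ifit3 (2.22 ± 0.34). Marco (-1.27 ± 0.15) fell, as did, with the difference in sex markers, Y-linked Ddx3y (-2.11 ± 0.45) and Eif2s3y (-1.49 ± 0.31). Of the interferon-stimulated genes, 26 of 39 rose and 38 did so adjusted over the list alone (adjusted p = 3.32e-41, and adjusted p = 0.407 with an estimated correlation). The count was 320, 94 and 52 without anti-PD-L1 replicates 1, 2 and 3. It was 12, 59 and 44 without combination replicates 1, 2 and 3. Only the 6 libraries compared gave 8, no filter 78 and limma-voom 319. Of 23 named genes that passed, 16 lost their call with at least 1 library left out, and 16 with only the 6 libraries compared, Oas2, Irf7 and Ifit3 among the latter. Without combination replicate 1 the adjusted p reached 0.0529 for Irf7, 0.0711 for Ifit3, 0.152 for Ddx3y and 0.142 for Eif2s3y. Ddx3y itself ranged from 3.27 to 3.44 with anti-PD-L1 and was at most 0.00774 with the combination. Its standard error takes the spread of all 12 tumor libraries, which include PBS replicate 1 at 3.55.

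Adding anti-PD-L1 to LNP-CDN changed 0 of 13173 genes in tumors by limma, with 680 at an unadjusted p under 0.05 and 0 by limma-voom. Ifit1 differed by 0.28 ± 0.37, Cd274 by 0.10 ± 0.24 and Gzmb by -0.15 ± 0.51. Interferon-stimulated genes were higher as a list, with 0 of 39 passing and 0 adjusted over the list alone (adjusted p = 6.71e-07, and adjusted p = 0.898 with an estimated correlation). Macrophage markers were higher as a list too, with 0 of 15 passing and 1 adjusted over the list alone (adjusted p = 0.00345, and adjusted p = 0.742 with an estimated correlation). Hypoxia and glycolysis genes were lower, with 0 of 15 passing and 0 adjusted over the list alone (adjusted p = 0.000125, and adjusted p = 0.898 with an estimated correlation). Immediate early and heat shock genes were lower as a list, with 0 of 14 passing and 9 adjusted over the list alone, such as Dusp1 (-0.76 ± 0.21) (adjusted p = 8.54e-12, and adjusted p = 0.742 with an estimated correlation). With no filter on low values 1 gene passed, Gm12262, named after its value was seen.

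**Figure D3:**
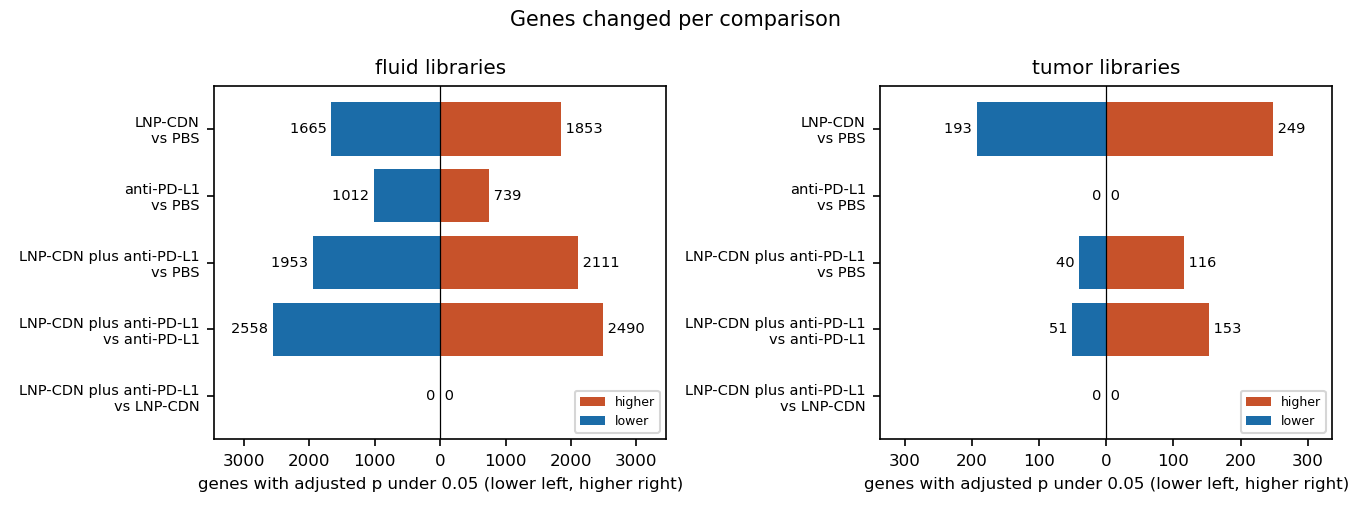
Number of genes with adjusted p under 0.05 (horizontal axes, lower to the left and higher to the right of 0) for the 5 comparisons between treatments, in fluid and in tumor libraries on separate scales. Bars for LNP-CDN against PBS reach 1853 higher and 1665 lower genes in fluid and 249 and 193 in tumor, while adding anti-PD-L1 to LNP-CDN in either tissue, and anti-PD-L1 against PBS in tumor, give 0.

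Under PBS, tumor and fluid cells differed in 11393 of 15222 genes, 5625 higher in tumor and 5768 lower. Scaling to total reads, chosen after seeing the data, moved the median of all genes from -0.01 to 0.27 and the split to 7474 higher and 4352 lower. Single genes lower in tumor were Arg1 (-4.60 ± 0.15), Cd163 (-5.33 ± 0.22), Cxcr2 (-5.76 ± 0.30) and Cd22 (-2.85 ± 0.13). The chemokine Cxcl9 was 6.40 ± 4.71 in tumor and 0.883 ± 0.0519 in fluid, and Cxcl10 5.35 ± 2.11 and 1.92 ± 0.688. Of the neutrophil markers, 16 of 16 were lower in tumor and 16 did so adjusted over the list alone (adjusted p = 2.43e-06, and adjusted p = 0.262 with an estimated correlation). Of the T cell markers, 16 of 16 were lower in tumor and 16 did so adjusted over the list alone (adjusted p = 0.000157, and adjusted p = 0.297 with an estimated correlation), and of the interferon-stimulated genes, 36 of 39 were lower in tumor and 36 did so adjusted over the list alone (adjusted p = 2.04e-07, and adjusted p = 0.357 with an estimated correlation). Of the endothelial markers, 11 of 11 were higher in tumor and 11 did so adjusted over the list alone, such as Plvap (3.11 ± 0.16) (adjusted p = 2.46e-05, and adjusted p = 0.262 with an estimated correlation). Of the fibroblast markers, 12 of 15 were higher in tumor and 12 did so adjusted over the list alone, such as Lum (4.08 ± 0.27) (adjusted p = 0.000266, and adjusted p = 0.262 with an estimated correlation). Of the cell cycle genes, 24 of 24 were higher in tumor and 24 did so adjusted over the list alone, such as Cdk1 (1.87 ± 0.14) (adjusted p = 2.04e-07, and adjusted p = 0.331 with an estimated correlation). The tissues also differ in how the cells were obtained, since tumors were digested with enzymes.

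Whether a treatment acted differently in the tissues was tested as the tumor change minus the fluid change. For LNP-CDN, 2323 genes differed, 1197 with a higher and 1126 with a lower change in tumor, and without tumor PBS replicate 1 the larger side turned, to 869 and 922, as it did without fluid PBS replicate 3, to 782 and 798. Interferon-stimulated genes changed less in tumor, with 18 of 39 passing and 19 adjusted over the list alone (adjusted p = 3.04e-09, and adjusted p = 0.449 with an estimated correlation). B cell markers had a higher change in tumor, 10 of 11, and 10 adjusted over the list alone (adjusted p = 1.16e-09, and adjusted p = 0.143 with an estimated correlation). Those markers fell in fluid, so a higher change in tumor is not by itself a rise there. Most interferon-stimulated genes were lower in tumor than in fluid under PBS, as was the B cell gene Cd22. Changes of low genes are understated on this scale, and how far that sets these differences was not tested. For the combination 2287 genes differed, 1196 and 1091. For anti-PD-L1, with sex markers as above, 808 differed, 545 and 263. That count was 492 without fluid PBS replicate 1, 479 without fluid PBS replicate 3, 519 without tumor PBS replicate 2, 514 with a pseudocount of 0.1 and 474 by limma-voom. Regulatory T cell markers gave 5 of 6 with a higher change in tumor, 5 adjusted over the list alone (adjusted p = 3.07e-06, and adjusted p = 0.00418 with an estimated correlation). Of the mature migratory dendritic cell genes, 7 of 11 had a higher change in tumor, 9 adjusted over the list alone (adjusted p = 1.45e-11, and adjusted p = 0.0467 with an estimated correlation). Both lists were also called in fluid for anti-PD-L1 against PBS with the preset correlation, though not with an estimated one. The regulatory T cell markers fell there. The T cell marker list was called too, in fluid and in this tissue difference, with the preset correlation only. In tumor, anti-PD-L1 against PBS gave 0 changed genes.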

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

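The interaction tests of tissue by treatment were planned, and the counts of other splits of the libraries were written down only after they had been computed. The change with LNP-CDN differed between tissues for 2323 genes by the test of the difference. Values are the tumor change minus the fluid change. The largest were Alas2 (3.94 ± 0.55), Cd79a (3.33 ± 0.62) and Lyve1 (3.26 ± 0.62) on the higher side and Ifit2 (-3.92 ± 0.47), Gpnmb (-3.86 ± 0.23) and Ifit1bl1 (-2.96 ± 0.44) on the lower side. Alas2, Cd79a and Lyve1 were among the large decreases in fluid, and Ifit2, Gpnmb and Ifit1bl1 among the large increases there. For the combination, 2287 genes differed, led by Alas2 (3.98 ± 0.55), Lyve1 (3.48 ± 0.62), H19 (3.21 ± 0.38), Ifit2 (-3.64 ± 0.47), Ifit1bl1 (-3.50 ± 0.44) and Gpnmb (-3.44 ± 0.23). For anti-PD-L1, 808 genes differed, led by Ppbp (3.23 ± 0.68), Mir7027 (2.90 ± 0.83), Mir511 (2.77 ± 0.52), Y-linked Eif2s3y (-3.26 ± 0.33), Mir6400 (-3.18 ± 0.40) and Y-linked Ddx3y (-3.17 ± 0.48). Mir7027, Mir511 and Mir6400 are short microRNA genes, whose values rest on few reads, and Mir7027 reached adjusted p = 0.127 without fluid PBS replicate 1. By limma-voom, chosen after seeing the data, Cd79a and Ifit1bl1 for LNP-CDN, Ifit1bl1 for the combination, and Mir7027, Mir511 and Ddx3y for anti-PD-L1 were not past the threshold. No outlier test was run on groups of 3 libraries.

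Other splits of the same libraries do not decide on chance for these tissue differences, since some keep the real fluid groups and so the fluid effect. As many genes came from 7 of 100 splits for LNP-CDN, 10 for anti-PD-L1 and 7 for the combination, the real split included. The highest other splits gave 3547, 1602 and 3943 genes against real counts of 2323, 808 and 2287. Of the splits as large other than the real one, 6, 9 and 6 kept the real fluid groups, which keeps the fluid effect in the contrast. With any other fluid grouping, the highest counts were 23, 11 and 4.

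With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, so only the values are given. The real count and the highest of the other splits in fluid were 3518 and 2 for LNP-CDN against PBS, 1751 and 0 for anti-PD-L1 against PBS, 4064 and 0 for the combination against PBS, 5048 and 0 for the combination against anti-PD-L1, 0 and 0 for the combination against LNP-CDN. In tumor they were 442 and 0 for LNP-CDN against PBS, 0 and 4 for anti-PD-L1 against PBS, 156 and 0 for the combination against PBS, 204 and 0 for the combination against anti-PD-L1, 0 and 1 for the combination against LNP-CDN. For tumor against fluid under PBS they were 11393 and 0. Where genes were called, 1 of 10 splits, the real one, gave as many. Where the real count was 0, 10 of 10 did, which holds by definition. A split that mixes differing groups adds their difference to the spread, so its low count says little about chance.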

How the results depend on the processing

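Of 122 pairs of a count and a setting other than a left-out library, 103 stayed within 1.5 times the main count and 19 moved further. Limma-voom, total-read scaling, keeping the affected genes and leaving out X and Y were chosen after seeing the data. Some settings could hardly move a count. Rescaling by median of ratios nearly repeats the deposited scaling, and keeping the affected genes or leaving out X and Y touches few genes. The share that stayed therefore does not measure how firm the counts are. No filter on low values, which tests more genes, gave 2 for the combination against LNP-CDN in fluid, and in tumor 98 for LNP-CDN against PBS, 1 for anti-PD-L1 against PBS, 52 for the combination against PBS, 78 against anti-PD-L1 and 1 against LNP-CDN. Only the 6 libraries compared, which leaves fewer samples for the spread and applies the filter anew (12594 genes tested for anti-PD-L1 against PBS in fluid), gave 1043 for anti-PD-L1 against PBS and 4 for the combination against LNP-CDN in fluid, and in tumor 106 for LNP-CDN and 2 for anti-PD-L1 against PBS and 8 for the combination against anti-PD-L1. A pseudocount of 0.1 gave 1 for the combination against LNP-CDN in fluid and 514 for the tissue difference with anti-PD-L1. Limma-voom gave 264 and 319 for the combination against PBS and against anti-PD-L1 in tumor and 474 for that tissue difference; the cause of the shifts with the 6 libraries, the pseudocount and voom was not tested. With 1 library left out, counts ranged over 2202 to 2831 (LNP-CDN) and 724 to 1789 (anti-PD-L1) against PBS in fluid. In tumor they ranged over 24 to 567 (LNP-CDN), 0 to 2 (anti-PD-L1) and 25 to 116 (combination) against PBS and 12 to 320 for the combination against anti-PD-L1. For the tissue difference with anti-PD-L1 the range was 479 to 1035.

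The replicate block gave 165 genes for LNP-CDN against PBS, 93 for the combination against PBS and 104 for the combination against anti-PD-L1 in tumor, and moved no other count by over 1.5 times. Whether the numbers pair the libraries is not settled by the labels or by these values. No comparison had every same-numbered correlation of deviations above 0.1, and the lowest was -0.114. With 3 libraries per group, paired libraries could also fall short of that. In fluid, each combination library correlated best with the LNP-CDN library of its own number. Each fluid LNP-CDN library did so with the tumor library of its own number. The reverse direction was not checked. These were the only full matches among many such checks, come from the data and not the design, and do not decide on pairing. None of 509 named gene results past the threshold changed direction under the settings run. These results were chosen for passing on the same libraries, so a change of direction was unlikely from the start. With 1 library left out, some fell below the filter and were not tested. Of the 509, 89 lost their call in at least 1 such run and 420 kept it wherever they were tested. With no filter 58 lost it, with only the 6 libraries compared 44 of 388, and with limma-voom 11. Of 218 list calls, 164 were kept with each library left out, 3 with an estimated correlation, and 2 changed direction with a library left out.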

Other observations

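The genes named here beyond the core genes, and all tests in this part other than those of single genes and lists, were chosen after the values were seen. In fluid with LNP-CDN against PBS, of the mast cell markers 3 of 5 rose and 3 did so adjusted over the list alone, while 2 fell, and camera did not call the list (adjusted p = 0.276, and adjusted p = 0.578 with an estimated correlation). The granule proteases Cma1 and Cpa3 were 0.452 ± 0.232 and 0.627 ± 0.228 in PBS, 4.57 ± 0.881 and 3.01 ± 0.527 with LNP-CDN, and 1.45 ± 0.488 and 0.713 ± 0.355 with both agents (SD, n = 3). H19 was 24.9 ± 4.54 in PBS tumors and 34.9 ± 2.61 in tumors with both agents, where fluid with both stood at 0.154 ± 0.00905. Gpnmb, which rose in fluid with LNP-CDN, was 21.2 ± 0.504 in PBS tumors and 19.8 ± 4.04 in LNP-CDN tumors. Acta1 of skeletal muscle ranged from 0.190 to 4.33 in PBS tumors, 1.48 to 34.7 with anti-PD-L1, 0.863 to 95.5 with LNP-CDN and 5.62 to 59.5 with both agents. Alb, a liver gene, was 27.8 in tumor anti-PD-L1 replicate 2, 15.3 in tumor LNP-CDN replicate 1 and 12.1 in fluid replicate 3 of the combination, and at most 0.614 in the other libraries. Of the genes left below the filter, Ifng in fluid was 0.165 ± 0.0324 in PBS and 0.745 ± 0.469 with LNP-CDN, and Foxp3 in fluid was 0.956 ± 0.0467 and 0.619 ± 0.173. Cd8a in tumor was 0.321 ± 0.244 and 0.681 ± 0.532, and Foxp3 in tumor 0.294 ± 0.0724 and 0.135 ± 0.00775.

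Values of 21 genes are not whole reads at their listed length, and 13 of them are in the gene lists (61.9% against 3.21% of other genes with an FPKM of at least 1 in at least 3 libraries, a filter not put to the affected genes). A listed length from another annotation is argued against by the 7 genes affected in both tissues, each of which needs a different length in fluid and in tumor. Where exactly 1 length makes the values whole, it is the exon length of a gene with no row used here in 95.5% of 22 sets, against 9.23% by chance. The values may therefore belong to other genes; how that came about was not tested, and no biological explanation was tested. As listed, Ifnb1 in fluid would read 4.72 ± 1.30 in PBS and 38.5 ± 7.43 with LNP-CDN, and Vegfa in tumor 28.9 ± 16.9 and 6.22 ± 0.897 in PBS and with both agents, so neither is used as a measure of that gene.

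Genes changed in fluid with anti-PD-L1 against PBS go with a difference in sex markers. Genes on chromosomes X and Y alone do not account for the count, since 1689 genes changed without them. The sex of the mice stays open: the lowest Ddx3y of the anti-PD-L1 libraries was 21.6, far above the PBS libraries, and the design confounds sex with treatment. The antibody stays open too, since 0 genes changed when it was added to LNP-CDN between groups that both lack Y-linked reads, where LNP-CDN is present on both sides. Sex and antibody cannot be told apart here for these genes.

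Y-linked reads in tumor PBS replicate 1 set it apart from the other PBS libraries. A swap with a tumor anti-PD-L1 library is argued against by the lowest Ddx3y of those 3 libraries, 3.27, since a partner without Y-linked reads is missing. Carry-over of a small amount of RNA from anti-PD-L1 tumors is argued against by a level of 107% of the tumor anti-PD-L1 mean. Carry-over from fluid anti-PD-L1 cells, where Ddx3y was 22.7 ± 0.999, was not tested. That the same mouse gave fluid PBS replicate 1 is argued against by a Ddx3y of 0.0253 there. A PBS mouse of the other sex, or a single wrong label, stays open and was not tested: Xist of 104 in that library does not decide, since tumor anti-PD-L1 libraries hold Y-linked reads beside Xist of 63.3 to 72.4.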
